A study of Rattus norvegicus with 8 samples.

How the data were processed

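Total RNA of endothelial cells from 8 rats, 4 given monocrotaline and 4 given saline, was read on 1-colour arrays, 1 array per rat. Per the labels, 10 ng of RNA was amplified and marked with Cy3, and the group of each sample was taken from its title and its injection entry. Per the file headers, all 8 arrays lay on 1 slide, were scanned on 1 day and were read with Agilent Feature Extraction 10.7.3.1. Per the file headers, the signal columns hold an intensity: the processed signal is background-subtracted and detrended within each array and is not scaled between arrays. The flag columns of those files hold other values, 0 or 1 per spot, per the file headers.

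The deposited value table is on a log2 scale, taken a second time. The submitters' processing notes name limma 3.6.9 without its role. Set against the scanner files, 2 to the power of each deposited value equals the quantile-normalized log2 processed signal over the 62976 features (median absolute difference 9.89e-10), so the deposited values served only as an alternative, with the second log2 undone.

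The analysis began from the processed signals. The mean over a probe's spots (1 to 10 per probe) was taken. Left out were the 4259 control spots and spots with a non-uniformity or population outlier flag on the array concerned. This dropped 17 of 30367 probes with all spots removed on at least 1 array. Log2 signals were scaled so that each array's 75th percentile is 0, which is the scale of every scaled log2 signal given here. A probe was kept when well above background, by the scanner software's flag, on at least 4 of 8 arrays, which left 21652 probes. The array files give no gene names, so probes were named through their accessions in a table of RefSeq accessions and symbols: 18006 probes matched 15159 symbols and 12361 did not match, among them all 3999 with Ensembl transcript accessions. For each gene the probe with the highest mean signal was used, giving 19137 genes, 11443 with a symbol and 7694 known by accession or probe ID. Genes such as Mki67, Top2a and Vwf had no probe matched.

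Monocrotaline was compared with saline in R 4.3.3 with limma 3.58.1 (linear model and moderated t-test, two-sided; files read with data.table, version 1.17.8). The p was adjusted by Benjamini and Hochberg over all genes tested. A gene was called at an adjusted p under 0.05, and at least 2-fold when its log2 fold change was also 1 or more either way. Gene lists, 23 of pathways and 19 of cell types, were written before the data were examined and tested when at least 5 genes were measured. Each was tested with camera (preset correlation of 0.01), with camera with an estimated correlation and with fry, and p was adjusted over the 42 lists. A list's members were also adjusted over the list alone. The score of an array is the mean log2 signal of a list's measured genes minus the saline mean, compared by a two-sided exact permutation test over the 70 regroupings. For a gene well above background on every array of one group and on none of the other, a lower bound of the fold is given. It sets the dim group no lower than each array's lowest signal well above background. It bounds the difference of means only and leaves out the spread between arrays, so it is no confidence limit.

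The naming rule took the 10 largest rises and falls among called genes with a symbol (not a provisional name) whose groups do not overlap and which are well above background on all 4 arrays of the brighter group. It added up to 3 called members of each list with the largest change or, where none was called, the member with the highest mean signal, and 7 genes fixed in advance (Pecam1, Bmpr2, Cdh5, Nos3, Edn1, Cdkn1a and Mdm2). The falls gave only 5. Of the genes that the rule picks, 2 are not reported here and none took their place, while the list counts and tests include them. Cd40lg, Ifng, Ccr4, Cd3d and Cd3g are exceptions, picked after their values were seen.

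The alternatives tried were normexp background correction with an offset of 50 followed by quantile or 75th percentile scaling, quantile normalization, median scaling, the deposited table, no filter, a filter requiring all 8 arrays, the mean of a gene's probes or each probe on its own, limma's trend and robust options, array weights, a block for replicate number, and leaving out each array. One was added after seeing the data, leaving out the 2 monocrotaline arrays with high airway cell genes. Normexp used the median spot signal because the files hold no mean signal. The pipeline was tested on simulated data of 21652 probes with 4 arrays per group: of 100 genes changed by 1 log2 unit 54% were called and of 100 changed by 2 units 81%, 0 with the wrong sign, 9 of 153 calls were of unchanged genes, and a null set gave 0 calls. The simulated probes varied independently of each other, unlike real genes, so the share of false calls need not hold for the real arrays. Between 70.8% and 77.7% of spots were well above background on each array, and the number of arrays, 4 per group, limits the precision. Figures were drawn with matplotlib 3.10.9 and pandas 2.3.3 in Python 3.11.15.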

Results

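Gene expression was measured in endothelial cells from the lungs of Sprague-Dawley rats aged 8 to 10 weeks, 5 days after a subcutaneous dose of monocrotaline (60 mg/kg) or of saline. Monocrotaline is a plant alkaloid that the liver turns into a reactive pyrrole able to bind DNA and protein in the lung vessels, and it is a standard way to bring on pulmonary arterial hypertension in rats. Each group held 4 rats. The cells were pulled out of digested whole lung with magnetic beads that bind CD31, an adhesion molecule of endothelial cells that platelets and some leukocytes carry too. RNA was taken from the beads without culture. The comparison asks which genes of the lung endothelium differ at this early stage of the model.

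Each sample was read on a 1-colour Cy3 array with 58717 non-control spots, and the number of arrays, 4 per group, limits the precision of every value. Between 70.8% and 77.7% of the spots were well above background. That share was 73.7% ± 2.4 (SD, n = 4) in the saline group and 76.5% ± 1.3 (SD, n = 4) in the monocrotaline group (two-sided exact permutation test, p = 0.114, where 0.0286 is the smallest p that 4 against 4 arrays allow). Across genes, the log2 signals of 2 arrays correlated at r = 0.965 to 0.986 within the saline group, at 0.971 to 0.981 within the monocrotaline group and at 0.962 to 0.979 between the groups. The first principal component held 28.5% of the variance and separated the groups (two-sided exact permutation test, p = 0.0286). All 8 arrays lay on 1 slide, with the saline samples in its row 1 and the monocrotaline samples in its row 2. Slide row and group thus cannot be told apart. Saline and monocrotaline arrays with the same replicate number shared a slide column.

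Of 24 DNA replication, 24 mitosis and 19 DNA repair genes 19, 12 and 6 rose in the monocrotaline samples, and so did 3 of 18 T and NK cell markers. Tested as lists by camera, the 4 had adjusted p = 0.142, 0.423, 0.0688 and 0.423 with an estimated correlation. Of 19137 genes tested, 262 rose and 12 fell (limma, Benjamini-Hochberg adjusted p under 0.05), and 229 and 5 of these changed at least 2-fold. In 37 of the 274 cases the gene belonged to the lists of mitosis, DNA replication or DNA repair genes fixed in advance. In each of the 274 genes all 4 monocrotaline arrays lay on one side of all 4 saline arrays. The test that picked them from these same arrays favours that, so it adds no support. Over all genes tested such a separation was seen in 8.44%, against 2.86% by chance. The median log2 fold change of all genes was -0.02. The 262 rises, with those of at least 2-fold in brackets, became 9 (9) without saline replicate 1, 112 (5 of them under 2-fold) without saline replicate 2 and 118 (117) without saline replicate 3. They became 109 (109) without saline replicate 4, 117 (112) without monocrotaline replicate 1 and 49 (48) without monocrotaline replicate 4. The 12 falls became 0 (0), 1 (1), 2 (2), 3 (2), 3 (3) and 1 (1) without those same arrays in that order. They became 87 (65) without monocrotaline replicate 2 and 6 (4) without monocrotaline replicate 3. With a block for replicate number, which is also a block for slide column, 0 genes rose and 0 fell.

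Among genes that met the naming rule, the largest rise was that of Stfa2l1, a stefin A-like gene of the cysteine protease inhibitors, which was well above background on 0 of 4 saline arrays and on 4 of 4 monocrotaline arrays and was at least 55.9-fold higher there (limma adjusted p = 0.0039). Csta, the stefin A gene, rose with a fitted log2 fold change of 3.82 ± 0.69 (SE, n = 4 per group, limma adjusted p = 0.0388). It was above background on only 1 saline array, so that size rests on signals near background. Clca1, best known as a secreted product of mucous airway cells, rose by 3.39 ± 0.62 and was above background on 2 saline arrays. Clca1 was highest on monocrotaline replicates 1 and 3 (scaled log2 signals of -3.91 and -3.003, against -5.84 and -4.75 on replicates 2 and 4), the arrays where airway cell markers were high too, at scores of 2.93 and 2.96 against 0.49. Without these 2 arrays, left out after seeing the data, its log2 fold change was 2.47 and it did not pass. That loss is not particular to Clca1, since 18 of the 25 named called genes lost their call with only 2 monocrotaline arrays left. Fosl1, a subunit of the AP-1 transcription factor, rose by 2.96 ± 0.40 and was above background on 2 saline arrays. The other 6 of the 10 largest rises included Ccne1 and Ccne2, the E-type cyclins that start DNA replication, and Cdca5, which keeps sister chromatids together. The rest were Cenpt, a kinetochore protein (2.98 ± 0.49), Mybl1, a transcription factor, and Neil3, a DNA glycosylase. Ccne1 went from a scaled log2 signal of -2.76 ± 0.25 (SD, n = 4) to 0.18 ± 0.63 (SD, n = 4), a 7.63-fold rise, and Ccne2, above background on 2 saline arrays, rose 10.3-fold. Cdca5, Neil3 and Mybl1 were not well above background on any saline array and were at least 8.14-fold, 6.59-fold and 5.21-fold higher after monocrotaline.

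**Figure D1:**
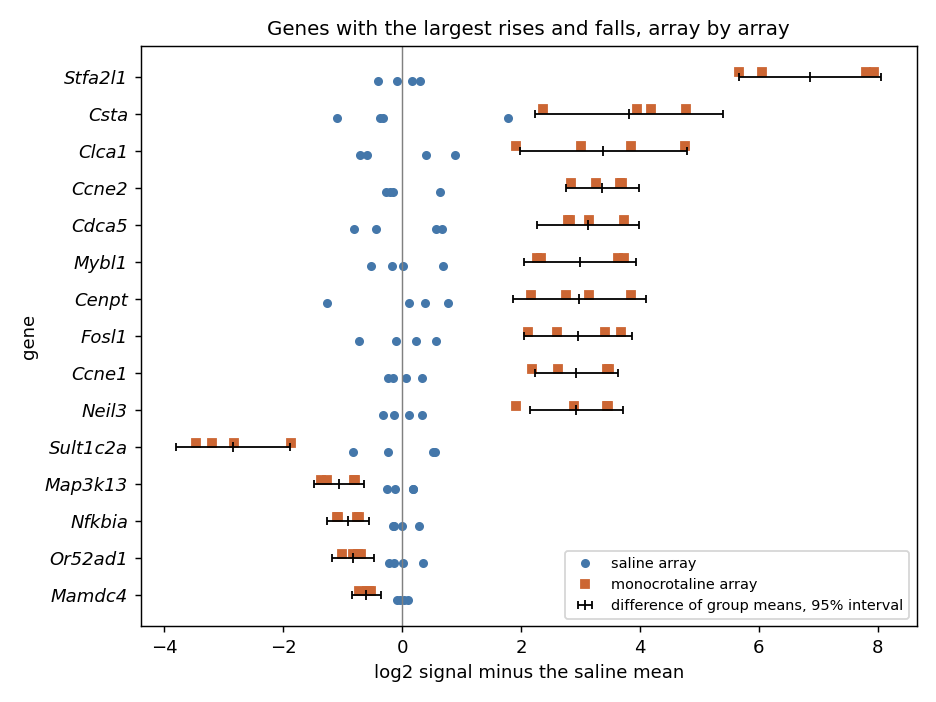
Log2 signal of each array minus the saline mean (x axis) for the 10 largest rises and the 5 falls that met the naming rule (y axis), with blue circles for saline arrays, orange squares for monocrotaline arrays and a black bar for the difference of group means with its 95% interval. In all 15 genes the groups do not overlap; Stfa2l1, Cdca5, Mybl1 and Neil3 were not well above background on any saline array and Sult1c2a on any monocrotaline array, so their plotted sizes are measured differences, not bounds.

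Among the falls, 5 met the naming rule. Sult1c2a, a cytosolic sulfotransferase, was above background on 4 saline arrays and on 0 monocrotaline arrays, and was at least 4.89-fold lower after monocrotaline (limma adjusted p = 0.0188). Nfkbia, the inhibitor of NF-kB that is itself an NF-kB target, fell by 0.92 on the log2 scale (SE 0.15, limma adjusted p = 0.0301). Map3k13, a kinase of the JNK pathway, had a log2 fold change of -1.06 ± 0.19, the olfactory receptor gene Or52ad1 of -0.82 ± 0.15 and Mamdc4 of -0.60 ± 0.11. Of the alternatives run for each, the call was lost in 13 of 20 for Nfkbia, 14 of 20 for Map3k13, 15 of 20 for Mamdc4, 17 of 20 for Or52ad1 and 8 of 19 for Sult1c2a. For Nfkbia these include quantile normalization, normexp with quantile normalization, the deposited table, no filter and leaving out any array but monocrotaline replicate 3, with log2 fold changes from -0.999 to -0.820 over all 20.

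With normexp background correction and 75th percentile scaling, which starts from the median spot signal and adds 50 after the correction, the log2 fold change was 3.23 for Stfa2l1, 1.84 for Ccne2, 1.34 for Fosl1, 1.24 for Csta, 1.18 for Clca1 and 1.01 for Cdca5. It was 0.75 for Neil3, 0.63 for Mybl1, -0.85 for Sult1c2a, -0.70 for Map3k13, -0.51 for Mamdc4 and -0.39 for Or52ad1. Of these 12 genes only Stfa2l1 and Ccne2 kept their calls. The order of the rises turned too: with that setting Ccne1 (2.75), Cenpt (2.58) and Cdc6 (2.12), which is not among the 10, lay above Csta, Clca1, Cdca5, Neil3 and Mybl1. Of the 25 called genes that this text names by its rule, 4, 8, 11 and 14 kept their calls without saline replicates 1, 2, 3 and 4. Without monocrotaline replicates 1, 2, 3 and 4 the number was 12, 21, 15 and 8.

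Most DNA replication genes rose. Of 24 measured S phase genes 19 rose and 0 fell (24 and 0 adjusted over the list alone), with a median log2 fold change of 1.34. Cdc6, which loads the replicative helicase, rose by 2.86 ± 0.25 (log2 fold change ± SE, n = 4 per group, limma adjusted p = 0.0061) next to Ccne1 and Ccne2. Of 24 measured mitosis genes 12 rose and 0 fell (22 and 0 adjusted over the list alone), with a median of 1.61. Nuf2, a kinetochore protein, rose by 2.06 ± 0.30, Hmmr, which binds spindle microtubules, by 2.05 ± 0.38, and Ccna2, cyclin A2, by 2.02 ± 0.32. Of 19 measured genes of DNA crosslink and double-strand break repair 6 rose and 0 fell (13 and 0 adjusted over the list alone), with a median of 0.71. Fancd2, of the Fanconi pathway that repairs DNA crosslinks, rose 4.13-fold. Brca1 was at least 4.23-fold higher, from 0 of 4 saline arrays above background to 4 of 4 monocrotaline arrays. With Brca1 at its bound the repair list's median stayed at 0.71.

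Against all other genes the 3 lists were shifted up by limma's camera with a preset correlation of 0.01, with adjusted p = 2.46e-36 for DNA replication, 1.63e-23 for mitosis and 4.33e-12 for repair. With an estimated correlation the adjusted p was 0.142 for DNA replication, 0.423 for mitosis and 0.0688 for repair. Limma's fry, which asks whether a list's genes move one way, gave adjusted p = 0.0015, 0.0434 and 0.0004. The mean of each list lay higher on all 4 monocrotaline arrays than on any saline array (two-sided exact permutation test, p = 0.0286, adjusted p = 0.20 over 42 lists). T cell markers were higher on the same monocrotaline arrays, with a mean T and NK cell score of 1.30 ± 0.42 (SD, n = 4) against the saline mean. The 19 S phase calls became 3 without saline replicate 1, 12 without saline replicate 2, 11 without saline replicate 3, 12 without monocrotaline replicate 1 and 8 without monocrotaline replicate 4. The 12 mitosis calls became 0 without saline replicate 1 or monocrotaline replicate 4, 1 without saline replicate 2, 3 or 4, and 4 without monocrotaline replicate 1. The 6 repair calls became 1 without saline replicate 1, 4 without saline replicate 3, saline replicate 4 or monocrotaline replicate 1, and 2 without monocrotaline replicate 4. Normexp with 75th percentile scaling gave Brca1 a log2 fold change of 0.38 and Hmmr one of 1.00, which did not pass, and Fancd2 one of 1.26, which did.

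**Figure D2:**
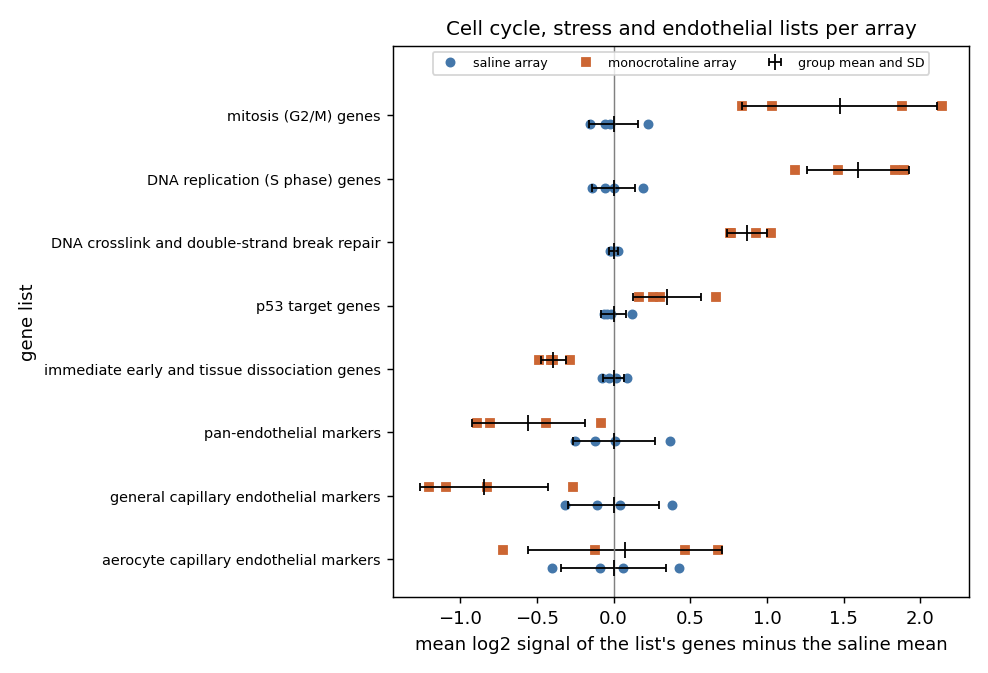
Mean log2 signal of each list's measured genes minus the saline mean (x axis) for 8 gene lists (y axis), with blue circles for saline arrays, orange squares for monocrotaline arrays and black bars for group mean and SD. The mitosis score lies between 0.84 and 2.14 on the monocrotaline arrays and between -0.15 and 0.23 on the saline arrays, while the aerocyte capillary scores of the groups overlap.

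Some T cell genes rose after monocrotaline. Of 18 measured T and NK cell markers 3 rose and 0 fell (14 and 0 adjusted over the list alone), all 18 had a positive log2 fold change, and the median was 1.30. Cd247, the zeta chain of the T cell receptor complex, rose by 2.11 ± 0.33 (log2 fold change ± SE, n = 4 per group, limma adjusted p = 0.0248), Cd8b, a coreceptor of cytotoxic T cells, by 1.67 ± 0.30 (adjusted p = 0.0388), and Zap70, a kinase of T cell receptor signalling, by 1.66 ± 0.27 (adjusted p = 0.0286). Camera's adjusted p was 5.58e-14 with the preset correlation and adjusted p = 0.423 with an estimated correlation, and fry's was 0.0622. The 3 calls became 0 without saline replicate 1, 2 or 3 or without monocrotaline replicate 3 or 4, 2 without saline replicate 4, 1 without monocrotaline replicate 1 and 5 without monocrotaline replicate 2.

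Markers of other leukocytes gave 0 calls. None of the 9 alveolar macrophage, 15 monocyte and interstitial macrophage, 8 neutrophil, 13 B and plasma cell, 9 platelet and 10 mast cell, basophil and eosinophil markers passed limma's test over all genes, and their medians were 0.03, -0.03, 0.52, 0.45, 0.25 and 0.31 (1 neutrophil marker was lower when adjusted over the list alone). At an unadjusted p under 0.05, 1302 genes of all kinds were higher and 1312 lower. Of these lists only the B and plasma cell markers were shifted by camera with the preset correlation (adjusted p = 0.0301), and it gave adjusted p = 0.897 with an estimated correlation. Camera's adjusted p was 0.966 for alveolar macrophages, 0.725 for monocytes, 0.662 for neutrophils, 0.308 for platelets and 0.0941 for mast cells, basophils and eosinophils. The B and plasma cell shift was lost without saline replicate 3 (0.244) or 4 (0.111) or monocrotaline replicate 2 (0.0680), 3 (0.1998) or 4 (0.0561). A shift appeared for monocytes without monocrotaline replicate 2 (0.0145), for platelets without monocrotaline replicate 3 (0.0137), and for mast cells, basophils and eosinophils without saline replicate 2 (0.0078) or monocrotaline replicate 4 (0.0450). The mean of the alveolar macrophage markers was -0.10 and that of the monocyte markers 0.14, opposite in sign to their medians. Examples by mean signal were Lyz2, lysozyme, at -0.34 ± 0.24 (log2 fold change ± SE), and S100a9, a neutrophil calcium-binding protein, at 0.86 ± 0.81. Gpnmb, a macrophage glycoprotein, was at 0.03 ± 0.81, Pf4, platelet factor 4, at 0.90 ± 0.55, and Mcpt8, a basophil protease, at 0.23 ± 0.27.

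Markers of airway, stromal and red cells differed between arrays of one group. The airway secretory and ciliated markers, 11 measured with 0 rises and 0 falls, had a median log2 fold change of 1.93, and their mean over the saline mean was 2.93 and 2.96 on monocrotaline replicates 1 and 3 but 0.49 on replicates 2 and 4. Camera gave them adjusted p = 0.0012 with the preset correlation and adjusted p = 0.723 with an estimated correlation. The erythroid markers, 7 measured with 0 calls, had a median of 1.31, and their score was 2.95 on monocrotaline replicate 3 against -0.15 to 0.81 on the other monocrotaline arrays (camera adjusted p = 0.0109, and adjusted p = 0.746 with an estimated correlation). The 12 fibroblast and mesothelial markers had a median of 1.03 (adjusted p = 0.0045, and adjusted p = 0.746 with an estimated correlation). The 16 smooth muscle and pericyte markers had one of 0.57 (adjusted p = 0.0241, and adjusted p = 0.897 with an estimated correlation), and either list had 0 calls. The brightest members had log2 fold changes of 1.07 ± 0.64 (Col1a2, a collagen of fibroblasts), 0.40 ± 0.66 (Actg2, a smooth muscle actin), -0.54 ± 0.26 (Tppp3, of ciliated cells) and 0.89 ± 0.59 (Hbb-b1, beta globin). Sparc, a matrix glycoprotein, was at -0.30 ± 0.21 and Clic5, of type 1 cells, at -0.40 ± 0.29. The 20 collagen and extracellular matrix genes had 0 calls and a median of 0.51 (adjusted p = 0.0461, and adjusted p = 0.90 with an estimated correlation). With 1 array left out, camera's shift was lost for the matrix genes without saline replicate 2 (adjusted p = 0.590) or monocrotaline replicate 1 (0.490) or 2 (0.151), and for smooth muscle and pericyte markers without the same arrays (0.518, 0.118 and 0.255). It was lost for fibroblast markers without saline replicate 2 (0.189), and for erythroid markers without saline replicate 2 (0.101) or monocrotaline replicate 3 (0.0850). Over all 20 alternatives camera's shift was lost in 1 for airway markers (adjusted p = 0.278) and in 4 for erythroid markers (up to 0.458). Alveolar type 2 and type 1 markers, 9 and 8 measured, had 0 calls and medians of 0.37 and 0.36, and camera adjusted p = 0.639 and 0.958, where camera's direction for the type 1 markers was down. Sftpc, the surfactant protein C gene of type 2 cells, spanned scaled log2 signals of 2.98 to 6.36 over the saline arrays and 5.11 to 5.94 over the monocrotaline arrays. Without monocrotaline replicates 1 and 3, left out after seeing their airway markers, 69 genes rose and 1 fell, among them 9 S phase, 3 mitosis, 3 repair and 0 T and NK cell genes. With 2 monocrotaline arrays left the log2 fold changes were 2.12 for Cd247, 1.59 for Cd8b, 1.66 for Zap70, 2.07 for Nuf2 and 2.05 for Ccna2, against 2.11, 1.67, 1.66, 2.06 and 2.02 with all 4. The median of the T and NK cell markers was 1.08, against 1.30.

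**Figure D3:**
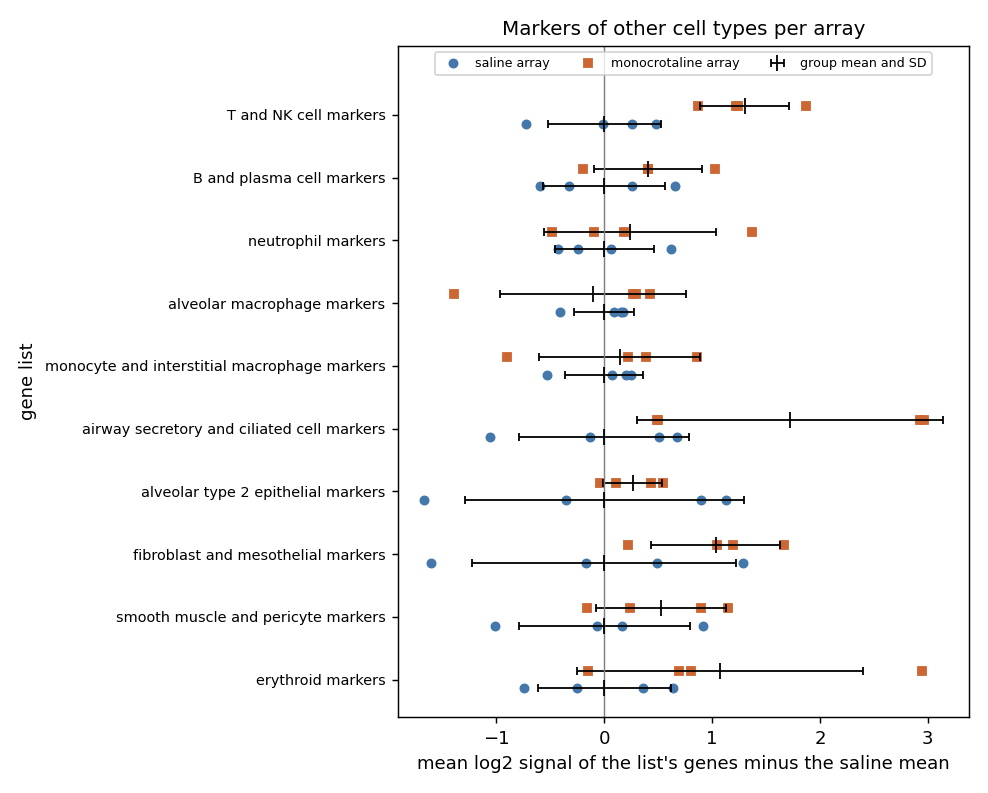
Mean log2 signal of each marker list's measured genes minus the saline mean (x axis) for 10 lists of other cell types (y axis), with blue circles for saline arrays, orange squares for monocrotaline arrays and black bars for group mean and SD. In the T and NK cell list the groups do not overlap, and the airway score stands near 3 (2.93 and 2.96) on 2 monocrotaline arrays and at 0.49 on the others.

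Lists of endothelial genes had lower medians, by a fold under 2, and their genes did not pass the test 1 by 1. All 17 measured pan-endothelial markers and all 8 general capillary markers had negative log2 fold changes, with medians of -0.58 and -0.88, and 0 in either list passed over all genes (2 and 7 fell when adjusted over the list alone). Pecam1, the CD31 gene on which the cells were selected, had a log2 fold change of -0.30 ± 0.19 (SE, n = 4 per group, limma adjusted p = 0.524), Cdh5, VE-cadherin of endothelial junctions, of -0.47 ± 0.25 (adjusted p = 0.447). Kdr, a VEGF receptor, had one of -0.15 ± 0.25 and Plvap, of fenestral and caveolar diaphragms, one of -0.50 ± 0.18. Ccl21, a lymphatic chemokine, had one of -0.64 ± 0.21, Mgp, an arterial matrix protein, one of 0.04 ± 0.29, and Vcam1, of the venous list, one of 0.25 ± 0.27. Camera with the preset correlation shifted the pan-endothelial (adjusted p = 3.33e-06), general capillary (7.54e-06), junction and barrier (1.41e-05), lymphatic (0.0045) and arterial (0.0179) lists down. With an estimated correlation their adjusted p was 0.723, 0.496, 0.723, 0.576 and 0.746 in that order. The medians of the junction, lymphatic and arterial lists were -0.42, -0.52 and -0.50, with 18, 6 and 10 genes measured and 0 called. The 9 aerocyte capillary and 5 venous markers, also with 0 calls, had medians of -0.04 and -0.12, camera adjusted p = 0.857 and 0.639, and the aerocyte mean was 0.08, opposite in sign to its median. The arterial shift was lost without saline replicate 4 (adjusted p = 0.108) or monocrotaline replicate 3 (0.0651). In all, camera's arterial shift was lost in 4 of 20 alternatives (adjusted p of up to 0.278) and its lymphatic shift in 1 of 20 (0.354). On the monocrotaline arrays T and NK cell markers were higher (score 1.30 ± 0.42, SD, n = 4) and airway markers were high on 2 of 4.

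Signalling genes tied to pulmonary hypertension showed 0 calls by limma over all genes. Bmpr2, the BMP receptor mutated in heritable disease, had a log2 fold change of -0.64 ± 0.26 (SE, n = 4 per group, adjusted p = 0.343), and Acvrl1, another BMP receptor of endothelium, of -0.42 ± 0.22 (adjusted p = 0.438). Nos3, the endothelial nitric oxide synthase, had one of -0.08 ± 0.21 (adjusted p = 0.902), and Edn1, the endothelin 1 gene, of -0.39 ± 0.24 (adjusted p = 0.510). The 23 BMP pathway genes had a median of -0.42, with 0 calls over all genes (0 higher and 1 lower adjusted over the list alone), and camera's adjusted p was 0.0069, or adjusted p = 0.746 with an estimated correlation. The 14 Notch genes had a median of -0.30 (adjusted p = 0.0158, and adjusted p = 0.746 with an estimated correlation). The 18 VEGF and angiopoietin genes had one of -0.26 (adjusted p = 0.0398, and adjusted p = 0.897 with an estimated correlation), with 0 calls in both. Of the BMP, Notch and VEGF genes 1, 3 and 9 stand in another list too. On the same arrays all 17 pan-endothelial markers had negative log2 fold changes (median -0.58, 0 called), and the T and NK cell score was 1.30 ± 0.42 (SD, n = 4) over the saline mean. The 20 TGF-beta and activin genes and the 23 vasoactive genes had medians of 0.02 and -0.08, with 0 calls and camera adjusted p = 0.497 and 0.510. Pmepa1, a TGF-beta target, was at -0.09 ± 0.20, Cav1, caveolin 1, at -0.30 ± 0.18, and Mfng, a Notch modifier, at -0.21 ± 0.13. Camera's shift was lost for the BMP list without monocrotaline replicate 3 (adjusted p = 0.183) and for Notch without saline replicate 4 (0.139) or monocrotaline replicate 3 (0.0850). It was lost for VEGF without saline replicate 3 (0.0929) or 4 (0.243) or monocrotaline replicate 3 (0.440) or 4 (0.105). In all, the VEGF shift was lost in 13 of 20 alternatives, with an adjusted p of up to 0.549. The BMP shift was lost in 3 of 20 (up to 0.471) and the Notch shift in 4 of 20 (up to 0.354).

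Of the 25 measured p53 targets 0 passed over all genes, while 5 were higher and 1 lower when adjusted over the list alone, and the list's median was 0.19. Camera's adjusted p was 0.0267 with the preset correlation and adjusted p = 0.496 with an estimated correlation. Its shift was lost in 3 of 20 alternatives, with an adjusted p of up to 0.129. Among these were leaving out saline replicate 2 (adjusted p = 0.0779) and monocrotaline replicate 1 (0.0714). Mdm2, the ubiquitin ligase that p53 induces, had a log2 fold change of 0.78 ± 0.21 (SE, n = 4 per group, limma adjusted p = 0.143). Cdkn1a, the p21 cell cycle inhibitor, gave -0.04 ± 0.25 at its brighter probe (adjusted p = 0.962) and 2.48 ± 0.51 at its other probe (adjusted p = 0.0604 when every probe was tested on its own). Its probes thus disagreed. Of 20 leukocyte adhesion and chemokine genes Ccl2, a monocyte chemokine, rose by 0.92 ± 0.16 (adjusted p = 0.0377) and Nfkbia fell. Ccl2 lost its call in 11 of 20 alternatives, among them median scaling, no filter and leaving out any array but saline replicate 4, with log2 fold changes from 0.79 to 1.03 over all 20. The other 18 did not pass. Adjusted over the list alone, 3 of the 20 were higher, Ccl2 among them, and 1 was lower, which was Nfkbia. The median of the 20 was -0.12 and their mean -0.07, while camera's direction was up (adjusted p = 0.805). The 21 immediate early and tissue dissociation genes, which also answer to cell handling, all had negative log2 fold changes, with 0 calls and a median of -0.36. Junb, an AP-1 subunit of that list, had one of -0.35 ± 0.14. Camera shifted this list down (adjusted p = 1.05e-05, and adjusted p = 0.149 with an estimated correlation), and fry's adjusted p was 0.0099.

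A gene was well above background on all 4 arrays of one group and on none of the other in 47 cases for monocrotaline and in 2 for saline. These counts carry no test. The bounds of the 47 ran from 55.9-fold down to 1.34-fold, where the gene did not pass (limma adjusted p = 0.439). The share of all spots above background was also higher in the monocrotaline group, at 76.5% against 73.7% (two-sided exact permutation test, p = 0.114), which bears on these counts. Beside the 5 genes named above, the 47 held Cd40lg, the CD40 ligand of activated T cells, at least 3.41-fold higher (limma adjusted p = 0.0391), and Ifng, interferon gamma, at least 2.73-fold higher, which did not pass (adjusted p = 0.0826), both picked after their values were seen. The 2 saline cases were Sult1c2a and a transcript known by its accession. The 47 became 142 without saline replicate 3, 74 without saline replicate 4, 103 without monocrotaline replicate 1 and 75 without monocrotaline replicate 2. They became 29 with the looser flag of a signal above background (positive and significant). The 2 became 8 without saline replicate 2, 7 without saline replicate 3, 5 without monocrotaline replicate 1, 7 without monocrotaline replicate 3 and 4 without monocrotaline replicate 4.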

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

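The tests of dividing T cells and both tests of a lower share of endothelial cells were chosen after the results were seen, and the others were not.

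In 14 of 220 groups of 4 arrays (6.36%) 1 array lay far from the other 3, by a gap that is a large part of the group's range; chance alone picks out about 1 in 20 groups. Among list scores, leukocyte adhesion was -0.40 on saline replicate 3 (nearest other array 0.09), coagulation 0.48 on monocrotaline replicate 1 (0.13), and venous markers 0.46 on monocrotaline replicate 2 (-0.47). The alveolar macrophage score was -0.41 on saline replicate 4 (0.09) and -1.40 on monocrotaline replicate 2 (0.26). Among scaled log2 signals, saline replicate 4 stood apart for Ccne2 at -5.60 (-6.39), Cav1 at 5.62 (5.16), S100a4 at 3.67 (4.40), Gpnmb at 2.30 (3.38) and Zap70 at -1.76 (-0.82). Monocrotaline replicate 2 stood apart for Vcam1 at 2.84 (1.89), Ccl21 at 5.45 (4.66) and Gpnmb at 0.50 (4.00), and saline replicate 2 for Lyz2 at 6.98 (6.27).

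The real grouping called 274 genes, 234 of them at least 2-fold, and the highest count among the other splits was 0 for both. So 1 of 35 splits gave as many, which argues against chance for these counts. It does not exclude chance, since 1 of 35 is the smallest share that the test can give. With camera's preset correlation the real grouping shifted 20 gene lists, but 9 of the 35 splits shifted as many, with 25 as the highest other. Chance thus cannot be excluded for the number of lists.

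Of 24 mitosis and 24 DNA replication genes 12 and 19 rose after monocrotaline, with a median log2 fold change of 1.41 over the 48, and camera gave adjusted p = 0.423 and 0.142 with an estimated correlation. A signal difference that raises dim probes is argued against, since the highest median among 10000 random lists matched on mean signal was 0.15. Dividing T and NK cells stay open: over the 4 monocrotaline arrays the T and NK cell score matched the mitosis score no better than most orders do (0.625 of the 24 pairings match as well or better), and 4 arrays are too few to decide. A candidate explanation in the design is the endothelium's own response to monocrotaline, which was not tested apart from other cell types. Slide row cannot be told apart from group, since each group filled its own row.

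Of 18 T and NK cell markers, 0 of which stand in another list, 3 rose after monocrotaline and 15 did not pass, all 18 with a positive log2 fold change, and camera gave adjusted p = 0.423 with an estimated correlation. A lower share of endothelial cells would raise all leukocyte markers alike if the mix of leukocytes stayed the same, which was not tested. The T and NK cell score exceeded the mean of 4 other leukocyte scores by 1.13 more after monocrotaline than after saline. The SD was 0.29 in saline and 0.25 in monocrotaline (exact permutation p = 0.0286, the smallest possible). This contrast was chosen after the T and NK cell markers were seen to stand out, so its p is no independent support. Markers of cells other than leukocytes also had positive medians, with 0 calls. These were 1.93 for airway, 1.31 for erythroid, 1.03 for fibroblast and mesothelial and 0.57 for smooth muscle and pericyte markers. A lower share of endothelial cells would raise those too, so the contrast does not decide whether it is the whole cause. The list's highest signals were those of Cd3d and Cd3g (means over the 8 arrays 1.20 and 0.82), both picked after their values were seen, which did not pass, at log2 fold changes of 1.78 ± 0.35 and 1.90 ± 0.38 (SE). More T cells in the lung or more of them held by the CD31 beads, which remove no CD31-bearing T cell, may both stand behind it and were not told apart. Slide row again equals group.

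The 17 pan-endothelial markers, 12 of which stand in other lists too, and the 8 general capillary markers had negative log2 fold changes, but 0 passed limma's test over all genes (2 and 7 adjusted over the list alone). Camera gave adjusted p = 0.723 and 0.496 with an estimated correlation, and the scores of the groups overlapped (exact permutation p = 0.0857 and 0.0571). A lower share of endothelial cells predicts that general and aerocyte capillary markers are lowered alike, if other cells add nothing to either list, which was not tested. The general score lay below the aerocyte score by a difference of -0.92 (SD 0.29 in saline and 0.70 in monocrotaline, exact permutation p = 0.0571), which does not decide. A lower share of endothelial cells and a change within them may both play a part, and these cannot be told apart with 4 arrays per group.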

How the results depend on the processing

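Leaving out the 2 monocrotaline arrays with high airway cell genes was chosen after seeing the data. Over the alternatives below 0 of the calls changed sign. Of 490 values of the 25 named called genes 294 kept their call, 196 lost it and 0 reversed. The lists of mitosis, DNA replication, repair, immediate early genes, junctions, pan-endothelial, general capillary and T and NK cell markers kept camera's preset shift under all 20 alternatives that refit the genes. Genes higher numbered 262 and lower 12, at least 2-fold 229 and 5, lists shifted 11 and 9, and 47 and 2 genes were above background in 1 group only. With normexp and quantile 29 were lower; with normexp and 75th percentile 152 were at least 2-fold higher. Quantile normalization and the deposited table each gave 9 at least 2-fold lower; median scaling gave 24 lower, 16 at least 2-fold, and moved the median of all genes from -0.02 to -0.11. No filter left 5 lists lower, and array weights gave 57 lower, 24 at least 2-fold. Without the 2 arrays, 69 genes were higher and 1 lower, 69 and 1 at least 2-fold, and 6 lists were shifted up and 4 down. Camera with an estimated correlation shifted 0 up and 0 down (3 and 1 at an unadjusted p under 0.05), and fry 3 and 1. The looser background flag left 29 genes above background in monocrotaline only. The VEGF list lost its shift in 13 of 20 alternatives: both normexp settings (0.0845 with quantile, 0.0794 with 75th percentile), quantile (0.0984), median scaling (0.0586), the deposited table (0.0921), no filter (0.131), array weights (0.0868) and the rest that block or leave out arrays. Without a filter the BMP (0.180), Notch (0.0982) and arterial (0.0856) lists lost theirs, and with array weights the matrix (0.152), B and plasma cell (0.0886) and erythroid (0.0886) lists. A shift appeared for ribosomal proteins with normexp and quantile (0.0042), quantile (0.0082) and the deposited table (0.0029). A shift also appeared for MHC class II genes with normexp and 75th percentile (0.0477), and for mast cells, basophils and eosinophils with median scaling (0.0454), array weights (0.0383) and the replicate block (0.0361). The cause was not tested for any of these.

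With 1 array left out, fewer samples enter and the counts ranged from 9 (without saline replicate 1) to 269 (without monocrotaline replicate 2) for higher, 0 to 87 for lower, 9 to 251 and 0 to 65 at least 2-fold, 5 to 10 for lists lower, and 51 to 142 and 2 to 8 for genes above background in 1 group only. Ccl21 passed without monocrotaline replicate 2 (-0.85, adjusted p = 0.0329).

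A block for replicate number left 0 genes higher and 0 lower, 0 and 0 at least 2-fold (limma, 1047 and 796 at an unadjusted p under 0.05). The numbers pair the arrays by slide column, so the block is a block for slide column too. Arrays with the same number had correlations of -0.02, -0.23, -0.33 and -0.20 after removing group means, none of them positive. Signal over background limits which genes were tested, with 21652 of 30367 probes kept, and the number of arrays limits the precision.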

Other observations

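Ccr4 and fry's mixed test were picked after their values were seen, and no other test in this part was.

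Lists of general cell state gave 0 calls by limma and 0 shifts by camera with the preset correlation (over all genes, 1302 were higher and 1312 lower at an unadjusted p under 0.05). Fry's mixed test, which lets a list's genes move either way, gave adjusted p = 5.43e-05 for unfolded protein response genes. It gave 0.0015 for cholesterol and 0.0477 for NRF2 genes. For hypoxia and for oxidative phosphorylation genes it gave 0.348, and for ribosomal protein genes 0.728. For the 22 hypoxia and glycolysis genes the median log2 fold change was -0.06 (camera adjusted p = 0.803), with Ldha, lactate dehydrogenase A, at 0.14 ± 0.13 (SE, n = 4 per group). The 26 oxidative phosphorylation genes had a median of -0.04 (adjusted p = 0.637) with Atp5f1a, an ATP synthase subunit, at -0.08 ± 0.11, and the 21 cholesterol genes one of 0.00 (0.664) with Msmo1, a sterol oxidase, at -0.19 ± 0.15. The 24 ribosomal protein genes had a median of 0.01 (0.662), and a shift appeared without saline replicate 2 (0.0026). The 19 NRF2 genes had a median of -0.02 and a mean of 0.07 (0.662), with Fth1, ferritin heavy chain, at -0.25 ± 0.20. The 23 unfolded protein response genes had a median of -0.03 and a mean of 0.11 (0.805; 1 lower adjusted over the list alone), with Atf4 at -0.17 ± 0.13.

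Of the 26 interferon-stimulated genes 0 passed, with a median of -0.16 (camera adjusted p = 0.257), and a shift down appeared without saline replicate 1 (0.0327) or 3 (0.0217); Ifi27 had a log2 fold change of -0.31 ± 0.16 (SE, n = 4 per group). The 10 MHC class II genes had a median of 0.23 (0.212), with a shift without saline replicate 2 (0.0083) and Cd74, the invariant chain, at 0.19 ± 0.35. The 13 genes of endothelial-to-mesenchymal transition had a median of 0.18 (0.299), with a shift without saline replicate 3 (0.0253), and S100a4 at -0.19 ± 0.24. The 14 coagulation genes had a median of -0.00 and a mean of 0.19 (0.892), with Thbd, thrombomodulin, at -0.38 ± 0.17. Ccr4, a chemokine receptor of T cells, was at least 3.30-fold higher (limma adjusted p = 0.107) and above background on 4 of 4 monocrotaline arrays and 0 of 4 saline arrays.

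In the deposited table log2 was taken a second time, so a difference of 2 groups in it is no log2 fold change: Cdc6 differed by 0.50 as deposited and by 2.77 after undoing 1 log2.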
